A study of Mus musculus with 72 samples.

How the data were processed

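Cortical RNA from 36 mice was measured with 2 NanoString nCounter panels, a hybridisation assay that counts fluorescent barcodes for a fixed set of transcripts without amplification. Each mouse was registered once for the Glial panel and once for the Neuropathology panel, which makes 72 records. All mice carried the 5xFAD transgenes, a set of human amyloid precursor protein and presenilin mutations that produces amyloid plaques. There were 3 genotypes: 5xFAD alone, 5xFAD with the M28L variant of Plcg2 and 5xFAD with the P522R variant of Plcg2. Each genotype had 6 females and 6 males at 7.5 months of age, and each mouse was a separate animal by its number in the labels. An exception in the numbering was a pair of female M28L mice that share the animal number 14 and differ in their index. Their recovered counts differed by a chi-square of 9.1 per gene over 692 genes, within the 2.3 to 95.0 of the 90 pairs of mice within groups. Without a repeat sample of a known animal to compare, this does not settle whether they are the same animal. Both were kept as separate mice, and entering them as their mean gave 129 called genes for M28L against 5xFAD in place of 130.

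The authors deposited log2 values, 1 column per mouse, in which the genes of both panels had been joined. Per the labels' protocols, total RNA was prepared with a PureLink kit and run by the standard NanoString procedure. The normalization behind the deposited values is not given in the sources used here. The table had 1517 rows, of which 251 named no gene and were left out, which leaves 1266 genes. Of these symbols, 1251 matched the GRCm38.p6 gene table directly, 3 matched after a dot was read as a hyphen, 6 matched as synonyms and 6 did not match. Among the unmatched is a probe shared by C4a and C4b, which cannot tell these near-identical genes apart.

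On the linear scale, 100.0% of the deposited values were whole multiples of 1 of 2 steps per mouse, within a tolerance of 0.05 counts. This gave back the counts behind the values and showed that each panel of each mouse had been multiplied by a constant. The steps also split the genes into a panel of 757 genes and a panel of 509 genes. The recovered totals ran from 237563 to 1957325 counts per mouse and panel. These counts served to describe depth and low values and to compare the mice numbered 14, and genes and lists were tested on the deposited log2 values, except in the alternatives named below.

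Differences were tested with limma 3.58.1 in R 4.3.3. The model had a mean for each genotype and sex, all 36 mice shared a spread per gene, and eBayes was run with a trend on mean expression. Genotype contrasts were averaged over the sexes, and further contrasts gave the effect within each sex, its difference between the sexes and the difference between females and males. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 1266 genes of a contrast, and an adjusted p of 0.05 was the threshold. Fold changes are differences of the deposited log2 values with no added pseudocount. A gene list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over 19 lists and 3 genotype comparisons, which is 57 tests. The same lists were tested with an estimated correlation and with fry, which asks whether the genes of a list move in a common direction without setting them against other genes. List scores per mouse are means over members of the log2 value minus the mean of the 5xFAD mice of the same sex. Scores were compared by permutation within sex with 100000 resamples.

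The groups, the tests, the 19 gene lists and the rule for named genes were fixed before the data were examined. Per genotype comparison the rule took Plcg2, Trem2, Tyrobp, Apoe and App where measured, the 10 largest rises and 10 largest falls among called genes, and up to 3 members with the smallest p from each list. For the sex comparison and the interactions it took the 5 smallest adjusted p. Where a count was under 10 genes the rule would also have taken the 10 smallest p. Plcg2 itself was not analysed here, and some genes that the rule takes are not reported here. Alternatives were median centring, quantile normalization, centring on 2 housekeeping genes, filters on low values, a pseudocount of 20, other variance models, fits without sex or without the third genotype, subsets of the M28L mice by index, a block for the index number, and leaving out each mouse in turn. Median centring within each panel, a filter at a mean of 20 counts, housekeeping centring of the sex, interaction and within-sex comparisons, and list tests without the third genotype were chosen after seeing the data.

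The fit was tested on simulated mice with the real genes' means and spreads and 200 changed genes in the comparison of M28L_5xFAD with 5xFAD over 1266 genes. It recovered 80.6% of genes changed by 1.25-fold, 86.6% of those changed by 1.5-fold and 100.0% of those changed by 2-fold, with 13 false calls among 191. With no list changed, camera called 1 of the 57 list tests. The simulated genes were drawn independently, whereas the estimated correlation in the disease-associated microglia list was 0.41 in the real mice. The simulation therefore does not show how often camera calls unchanged lists in the real mice. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.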

Results

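The study asked how 2 coding variants of Plcg2 act in an amyloid mouse model. Plcg2 encodes a phospholipase that signals downstream of TREM2 in microglia, the resident macrophages of the brain. In people, the P522R variant is associated with lower and the M28L variant with higher risk of Alzheimer's disease. Cortex of 12 mice per genotype, 6 of each sex, was profiled at 7.5 months for 1266 genes. Mice without the 5xFAD transgenes were not analysed here, so every comparison is between plaque-bearing mice.

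Depth followed sex and genotype. On the 757-gene panel the mean recovered total was 1125810 ± 96105 counts (SD, n = 6) in 5xFAD females and 1088008 ± 87241 (SD, n = 6) in M28L females. It was 1626764 ± 118687 (SD, n = 6) in 5xFAD males, 1669092 ± 50537 (SD, n = 6) in M28L males, 1738930 ± 229911 (SD, n = 6) in P522R females and 1702509 ± 73286 (SD, n = 6) in P522R males. The 100 dimmest genes had a median of 4.67 ± 0.52 counts (SD, n = 6) in 5xFAD females, 4.83 ± 0.41 (SD, n = 6) in M28L females and 13.83 ± 2.14 (SD, n = 6) in P522R females. In males these values were 10.0 ± 0.84 (SD, n = 6), 11.17 ± 0.68 (SD, n = 6) and 14.33 ± 1.63 (SD, n = 6). The first principal component, with 43.4% of the variance over well-measured genes, separated the sexes, and the second, with 30.3%, separated P522R mice from the other 2 genotypes. The 36 mice thus lay in 4 blocks, with 5xFAD and M28L mice of a sex together. The labels name no run or batch, so a P522R or sex difference cannot be told apart from a difference between runs. M28L and 5xFAD mice of a sex lay together on these 2 components, which does not show that they shared a run. The third component, with 5.6% of the variance, placed 5xFAD mice at 0.29 to 4.19 and M28L mice at -4.32 to 0.43. No label excludes a difference between runs for M28L mice either.

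**Figure D1:**
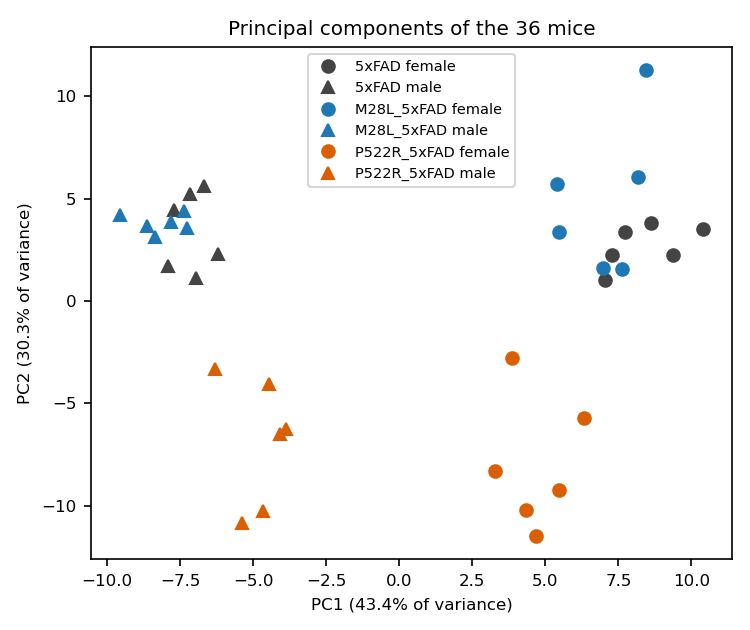
Principal components of the 36 mice over genes with a mean log2 value of 6 or more, PC1 on the x axis and PC2 on the y axis, each point a mouse coloured by genotype and shaped by sex. PC1 (43.4% of variance) separates females from males and PC2 (30.3%) places all P522R mice below the 5xFAD and M28L mice.

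Genes that microglia raise around amyloid plaques were among the largest falls in M28L mice. Itgax, which encodes the integrin CD11c, fell 2.64-fold (log2 fold change -1.40 ± 0.22 SE, adjusted p = 3.19e-05 with limma). Its log2 level went from 5.99 ± 0.30 in 5xFAD mice to 4.60 ± 0.67 in M28L mice (SD within sex, pooled over the sexes, n = 12 each). Gpnmb, a lysosomal glycoprotein, fell 2.55-fold, the chemokine gene Ccl3 2.40-fold, the invariant chain gene Cd74 2.28-fold and the NADPH oxidase gene Cybb 2.14-fold. The inhibitory receptor gene Lilrb4a, the cystatin gene Cst7, the olfactory receptor gene Olfr110 and the lectin gene Clec7a fell by 1.05, 0.97, 0.95 and 0.88 on the log2 scale. Of 1266 genes tested with limma, 130 changed in M28L mice against 5xFAD, with 71 lower and 59 higher. The median over all genes was 0.00, and 13 of the lower and 5 of the higher genes moved by more than 1.5-fold. A pseudocount of 20 took Itgax to -0.89 and Cybb to -0.67, both still called, and a fit without a sex term ended the call of Clec7a (adjusted p = 0.062).

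The disease-associated microglia list moved furthest. Of 30 measured members 18 fell and 0 rose, with a median log2 fold change of -0.36, and adjusted over the list alone 21 fell and 1 rose. All 12 M28L mice scored below the mean of the 5xFAD mice of their sex, at -0.44 ± 0.15 (SD, n = 12), and the permutation test within sex gave p = 2e-05 (adjusted p = 9e-05 over 9 such tests). Tyrobp, the signalling partner of TREM2, fell by 0.45 and Trem2 by 0.43 on the log2 scale (adjusted p = 0.00862 and 0.0227 with limma), each lower in 11 of 12 mice. Both calls ended without a sex term (adjusted p = 0.132 for Tyrobp and 0.0895 for Trem2) and with the M28L mice of index 1 to 3 (at -0.40 and -0.38, adjusted p = 0.0978 and 0.132), that of Trem2 also with index 7 to 9 (at -0.47, adjusted p = 0.0546), and centring on housekeeping genes took them to -0.29 and -0.26, still called. Among antigen presentation genes 6 of 8 fell (6 adjusted over the list alone), including H2.T23 at -0.30 and Tap1 at -0.44. Of 14 measured members of the complement and Fc receptor list 4 fell (adjusted over the list alone, 7 fell and 1 rose). Among them were Cd14 at -0.64, C3ar1 at -0.51 and Cd33 at -0.34. Of these named genes only C3ar1 encodes a complement receptor, and none encodes an Fc receptor. Of 23 lysosome genes 6 fell (10 adjusted over the list alone), with Cd68 at -0.54, Gusb at -0.47 and Ctsd at -0.40. Centring on housekeeping genes ended the calls of H2.T23, Tap1 and Cd33, at -0.14, -0.27 and -0.17 (adjusted p = 0.197, 0.0853 and 0.143), and took Gusb to -0.30 and Ctsd to -0.24, still called. The 2 genes of that centring were Gusb itself, at -0.47, and Tbp, at 0.14. The centred value of Gusb is therefore no check on its fall. The centring also moved the median of all genes to 0.17 in M28L mice, which lessens every fall. Calls also ended for Cd33 without a sex term (adjusted p = 0.0515) and with either index subset (0.0646 and 0.082), and with index 7 to 9 for Tap1 (at -0.22, adjusted p = 0.266) and Ctsd (adjusted p = 0.0729). Camera placed these 4 lists below other genes, with adjusted p of 3.5e-15, 0.000118, 0.000692 and 0.000939. With an estimated correlation camera called 0 of the 19 lists (3 had an unadjusted p under 0.05, and fry called 7), and these 4 had adjusted p = 0.313, 0.313, 0.58 and 0.843. The lists overlap, with 4 measured genes, among them Cd68 and Ctsd, in both the disease-associated microglia and the lysosome list.

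**Figure D2:**
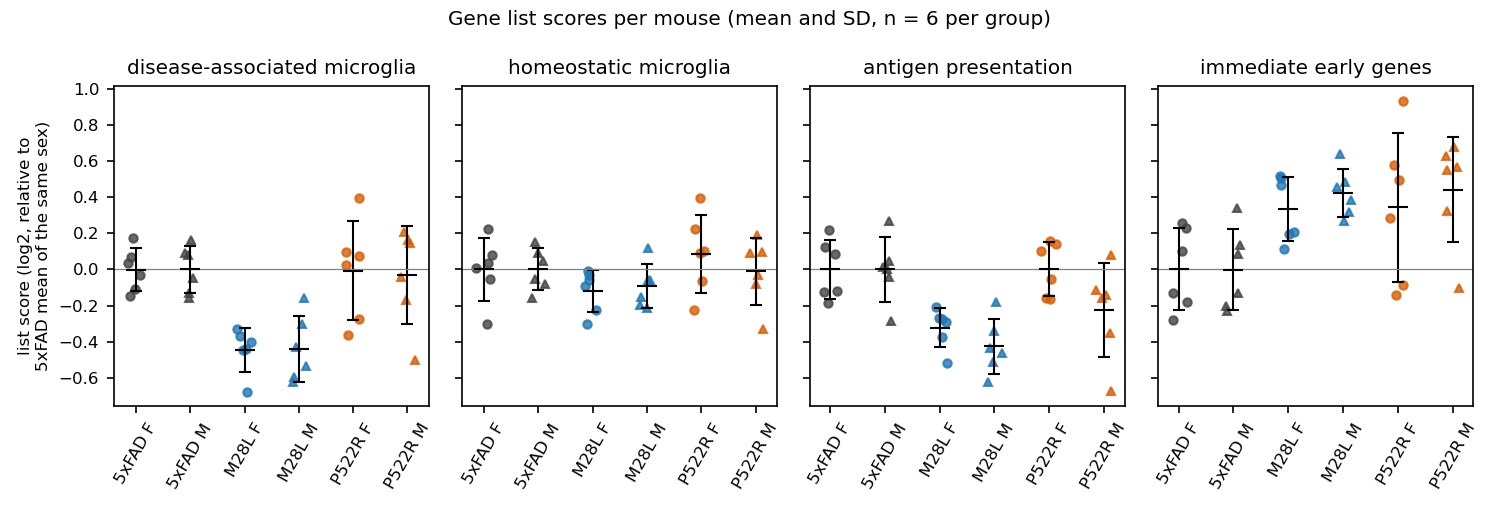
Scores of 4 gene lists per mouse, in log2 relative to the mean of the 5xFAD mice of the same sex, for the 6 groups of 6 mice on the x axis; points are mice, bars are mean and SD. All 12 M28L mice lie below 0 for disease-associated microglia and above 0 for immediate early genes.

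Homeostatic microglia genes changed less and in both directions. Of 21 measured members 2 fell and 1 rose (adjusted over the list alone, 3 fell and 1 rose), with Cx3cr1, the fractalkine receptor gene, at -0.42 and Tmem119 at 0.38, and the list as a whole was not called by camera (adjusted p = 0.175). The reactive astrocyte markers Gfap and Serpina3n fell by 0.38 and 0.54, and Hspb1, a small heat shock protein gene of that list, rose 1.69-fold; 3 of 24 members fell and 1 rose, against 4 and 1 adjusted over the list alone. The calls of Gfap and Serpina3n ended without a sex term (adjusted p = 0.334 and 0.132), with the M28L mice of index 1 to 3 (0.0896 and 0.137) and 7 to 9 (0.149 and 0.0762) and on leaving out some single mice, and that of Gfap also with housekeeping centring (at -0.21, adjusted p = 0.0736). Of 47 neuron and synapse genes 5 fell and 2 rose (7 and 2 adjusted over the list alone), with the AMPA receptor gene Gria3 at -0.17 and the calcium-binding protein gene Calb2 at 0.54. Centring on housekeeping genes took Gria3 to 0.00 (adjusted p = 0.985) and Cx3cr1 to -0.25, still called, and median centring within each panel took Gria3 to -0.11, still called. Without a sex term the calls of Tmem119, Hspb1, Gria3 and Calb2 ended (adjusted p = 0.1, 0.132, 0.224 and 0.1), and with index 1 to 3 those of Tmem119 and Calb2 (0.168 and 0.0614). Apoe was at 0.00 ± 0.08 (SE) and App at -0.11 ± 0.06 (SE), neither of which passed. No gene passed among the 8 interferon response, 9 astrocyte, 6 oligodendrocyte precursor and 15 lymphocyte genes (0 adjusted over the list alone in each). Signs differed for 3 lists without a call: the interferon response list had a median of 0.02 and a camera direction of down, the astrocyte list a median of 0.01, a mean of -0.02 and a direction of down, and the reactive astrocyte list a median of -0.04 and a direction of up.

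Some immediate early genes, which neurons switch on after activity, were higher in M28L mice. Arc rose 1.79-fold (log2 fold change 0.84 ± 0.17 SE, adjusted p = 0.000922 with limma), Egr1 rose 1.43-fold and Nr4a2 rose by 0.32 on the log2 scale, each above the 5xFAD mean of the same sex in 12 of 12 mice. Of 9 measured members 3 rose and 0 fell (5 and 0 adjusted over the list alone), the median was 0.32, and camera gave adjusted p = 0.000369 against an adjusted p = 0.515 with an estimated correlation. The stress-responsive cell cycle inhibitor gene Cdkn1a and the NF-kB inhibitor gene Nfkbia rose by 0.49 and 0.47. Pla2g4d, Fasl and Tnfrsf10b were among the 10 largest rises but had mean counts of 13, 14.8 and 11.9, where values lie near the floor of the assay. A pseudocount of 20 ended the calls of Pla2g4d and Tnfrsf10b, at 0.21 and 0.19 (adjusted p = 0.0706 and 0.118), and took Fasl from 0.74 to 0.26, still called; quantile normalization (0.61 and 0.49, adjusted p = 0.0636 and 0.155) and index 1 to 3 (adjusted p = 0.0779 and 0.151) also ended the first 2. All 3 calls ended without a sex term (adjusted p = 0.156, 0.127 and 0.345) and with index 7 to 9 (0.217, 0.22 and 0.113). Fitting genotype without sex left 30 called genes, 29 of them lower, and ended the calls of Arc, Egr1, Nr4a2, Cdkn1a and Nfkbia (adjusted p = 0.1, 0.132, 0.515, 0.1 and 0.0895). Centring on housekeeping genes gave 306 called genes, with 276 higher and 30 lower, as this centring moved the median of all genes to 0.17.

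**Figure D3:**
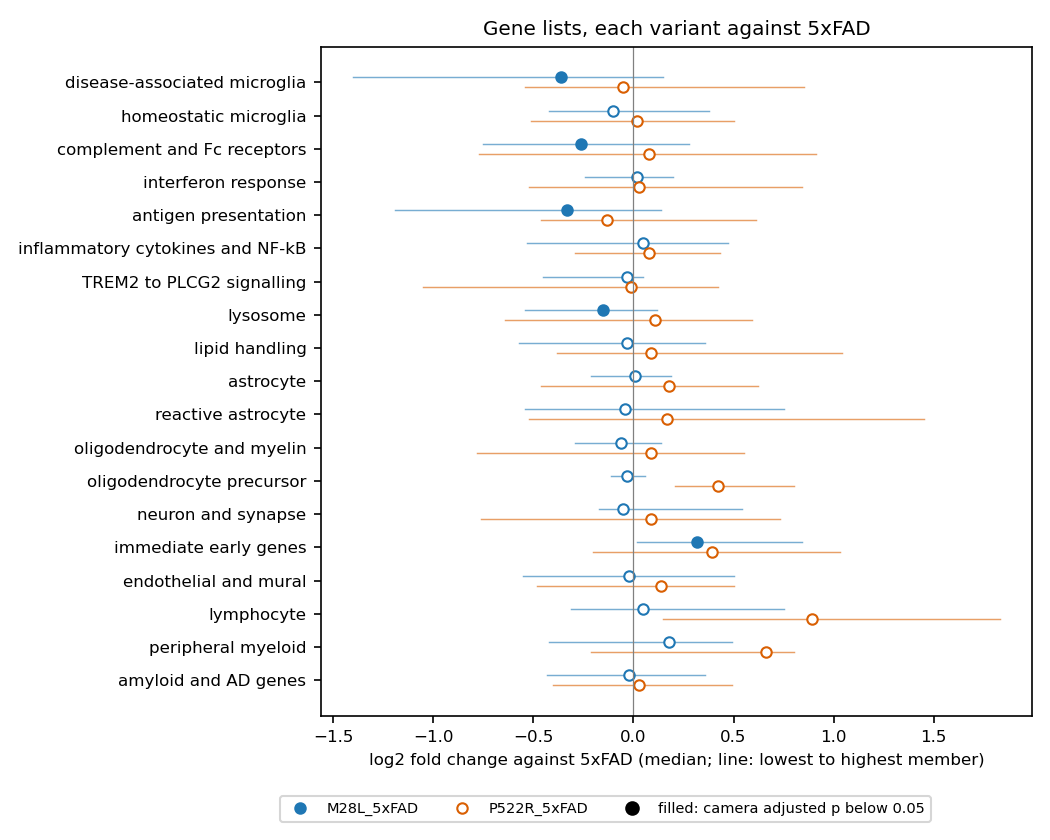
Median log2 fold change of each of the 19 gene lists (y axis) against 5xFAD (x axis), M28L in blue and P522R in orange, with a line from the lowest to the highest member and filled points where camera's adjusted p was below 0.05. In M28L mice 4 lists are called lower and 1 higher, and in P522R mice 0 are called; with an estimated correlation camera called 0 lists in either.

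In each sex the leading M28L differences ran the same way, and a difference between the sexes was not detectable in a single gene. Limma found 0 genes with an interaction of M28L and sex, and 34 of 1266 had an unadjusted p under 0.05. Itgax was at -1.36 in females and -1.43 in males, and Ccl3 at -1.22 and -1.30. Gpnmb was at -1.66 in females and -1.05 in males, and Cd74 at -0.82 and -1.55. Klrk1, Cysltr1, Il4, Fas and Trim17 had the smallest p for that interaction, with differences of 1.44, -0.95, -1.61, -1.11 and 0.51 that did not pass. Within a sex, 49 genes changed in females (24 higher, 25 lower) and 26 in males (11 higher, 15 lower). Median centring gave 17 higher and 34 lower in females, centring on housekeeping genes gave 252 and 18 there and 14 and 12 in males, and leaving out 5xFAD_F replicate 1248 or 1249 took the female count to 29 or 31 and M28L_5xFAD_M replicate 9 or 10 the male count to 15 or 17.

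P522R mice differed from 5xFAD mice in genes of many kinds. Each of the 19 lists had at least 1 called member, but with 65.4% of all genes called almost any list would. The protein kinase C genes Prkca and Prkcb fell by 1.21 and 1.05 on the log2 scale, and the kinesin gene Kif3a and the GABA receptor gene Gabrb2 by 0.92 each. The immediate early gene Egr1 rose 2.04-fold, the GABA synthesis genes Gad1 and Gad2 1.44-fold and 1.40-fold, and the lipoprotein receptor gene Lrp1 1.66-fold. App, which encodes the amyloid precursor protein, rose by 0.49 ± 0.06 (SE) and Bace1, the beta-secretase gene, by 0.45 ± 0.05 (SE), with adjusted p = 2.36e-08 and 7.33e-09 in limma, in 12 of 12 mice for App. In all, 828 of 1266 genes changed, 513 higher and 315 lower, with a median of 0.08 over all genes. These mice lay apart from the others as a block, as described above, and no value here separates the variant from that block.

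Microglial lists were split in P522R mice. Of 30 disease-associated microglia genes 8 rose and 8 fell (7 and 7 adjusted over the list alone), with Itgax at 0.85 and Gpnmb at 0.77 but Clec7a at -0.54, Fth1 at -0.50 and Serpine2 at -0.43. Quantile normalization took Fth1 to -0.10 and ended its call (adjusted p = 0.0799). Itgax, Gpnmb and Clec7a fall outside the naming rule for this comparison and were chosen after their values were seen. Trem2 fell by 0.31, Apoe by 0.38, and Tyrobp was at -0.24 without passing (adjusted p = 0.0629). Tyrobp passed with median centring (at -0.28, adjusted p = 0.022), median centring within each panel (at -0.30, adjusted p = 0.0145) and housekeeping centring (at -0.28, adjusted p = 0.0042), and the call of Trem2 ended without a sex term (adjusted p = 0.0605). Leaving out some single mice also ended the call of Trem2 or took Tyrobp past the threshold. Complement genes went apart, with the C4a and C4b probe 1.88-fold higher and C1qb and C1qa lower by 0.77 and 0.51, and 3 of 14 members of that list rose and 3 fell (2 and 3 adjusted over the list alone). A separate C4a probe on the other panel, looked up after the values were seen, stood at 0.37 ± 0.17 (SE, adjusted p = 0.0526 with limma), which did not pass. All 6 oligodendrocyte precursor genes rose (6 adjusted over the list alone), with Gpr17 at 0.80, Cspg4 at 0.61 and Pdgfra at 0.47, whereas the myelin genes Bcas1 and Mbp fell by 0.78 and 0.47. Of 47 neuron and synapse genes 23 rose and 13 fell (24 and 13 adjusted over the list alone). Of 15 lymphocyte genes 12 rose (12 adjusted over the list alone) with a median of 0.89, but 13 of the 15 had a mean under 20 counts; the T cell receptor gene Cd3d, at 1.83, had a mean of 10.1 counts. The mast cell gene Tpsb2, the largest rise at 1.86, had a mean of 4.4 counts. A pseudocount of 20 took Cd3d to 0.54 and Tpsb2 to 0.28, both still called, and quantile normalization took Cd3d to 1.08, still called, and Tpsb2 to 0.45 (adjusted p = 0.175). Camera called 0 of the 19 lists against 5xFAD and 2 had an unadjusted p under 0.05; with an estimated correlation it called 0, with 1 at an unadjusted p under 0.05, while fry called 8. The smallest camera adjusted p was 0.0744, for oligodendrocyte precursors and for lymphocytes, and with an estimated correlation these had adjusted p = 0.843 and 0.374. In P522R mice the homeostatic microglia, complement, oligodendrocyte and endothelial lists had medians above 0, of 0.02, 0.08, 0.09 and 0.14, and a camera direction of down.

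**Figure D4:**
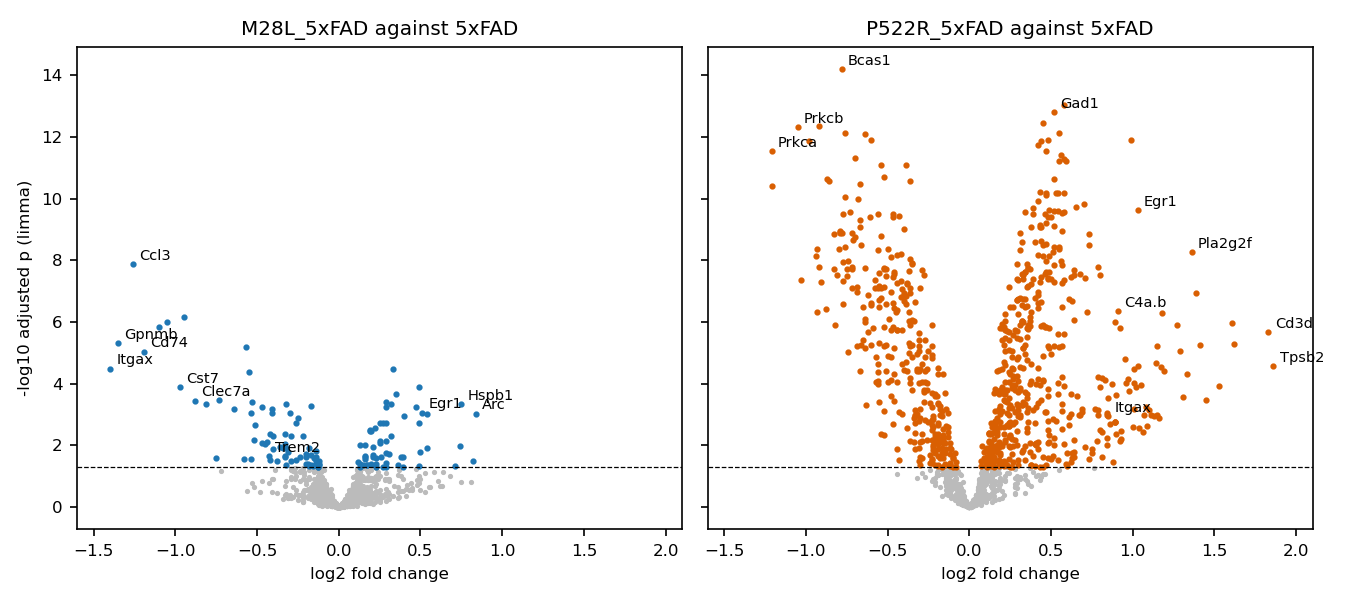
Log2 fold change (x axis) and -log10 of limma's adjusted p (y axis) for 1266 genes in each variant against 5xFAD, with called genes coloured and the dashed line at an adjusted p of 0.05. The left panel has 130 called genes and the right panel 828.

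Set directly against M28L mice, P522R mice had higher levels of some plaque-associated genes. Itgax was 4.74-fold higher (log2 difference 2.25 ± 0.22 SE, adjusted p = 6.29e-11 with limma), Gpnmb 4.34-fold, Lilrb4a 2.30-fold and the astrocyte gene Serpina3n 2.16-fold. Of 30 disease-associated microglia genes 20 were higher and 5 lower (20 and 5 adjusted over the list alone), with a median of 0.34, and camera did not call the list (adjusted p = 0.128, and adjusted p = 1 with an estimated correlation). Trem2 and Tyrobp differed by 0.12 ± 0.12 (SE) and 0.21 ± 0.12 (SE), which did not pass, though Tyrobp did on leaving out some single mice. Of 23 lysosome genes 14 were higher and 3 lower (14 and 3 adjusted over the list alone), with Man2b1 at 0.59 (0.39 with housekeeping centring, still called) and Npc2 at -0.76. Altogether 856 genes differed, 525 higher and 331 lower in P522R mice, and centring on housekeeping genes turned the balance to 183 higher and 483 lower with the median of all genes moving from 0.10 to -0.10. Camera called 0 lists, with 3 at an unadjusted p under 0.05, and fry called 12; the estimated correlation also gave 0, with 1 at an unadjusted p under 0.05. The cytokine and the immediate early gene lists had medians of 0.13 and 0.02 and a camera direction of down. The block that sets P522R mice apart enters this comparison in full.

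Against 5xFAD, the fold changes of the 2 variants correlated across genes with r = 0.25, genes not being independent replicates. That r became 0.05 with the filter at a mean log2 of 5, 0.10 with the filter at 20 counts and 0.15 with quantile normalization. Unchanged groups simulated against the same 12 5xFAD mice gave r = 0.50 ± 0.04 (SD over 100 simulations). The covariance was 0.0215 against 0.00573 in the simulation. With the 5xFAD mice split so that each variant had its own 6 controls, the mean r was 0.18 over 100 splits, from 0.02 to 0.29, and the mean covariance was 0.0162. Of the called genes 31 were higher in both variants, where independent lists would share 23.9, and 15 were lower in both, against 17.7. A further 31 were called in opposite directions, against 43.5 for independent lists, Itgax and Gpnmb among them, and Egr1 and Arc were higher in both.

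The P522R effect differed between the sexes for 264 genes, 199 with a higher value of the effect in females and 65 with a higher value in males. P522R females and P522R males lay in separate blocks, so this difference cannot be told apart from one between blocks. On the 757-gene panel the mean total was 1125810 counts in 5xFAD females and 1738930 in P522R females. In males these means were 1626764 and 1702509. The ubiquitin ligase gene Rnf10 was at 0.28 in females and -0.60 in males, the phosphatase gene Ptpn11 at 0.48 and -0.12, and Tln2 at 0.26 and -0.43. Atcay was at -0.23 and -0.96 and Camk2b at -0.04 and -0.66. After median centring 95 differences were higher and 163 lower in females, against 111 and 130 with quantile normalization, 130 and 90 with median centring within each panel and 56 and 0 with housekeeping centring. After median centring all 5 named genes were still positive, from 0.48 for Ptpn11 to 0.75 for Rnf10. Within females 762 genes changed (498 higher, 264 lower) and within males 640 (339 higher, 301 lower); median centring gave 359 higher and 373 lower in females, quantile normalization 356 and 326, and centring on housekeeping genes gave 156 higher and 263 lower in males.

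Females lay below males for most genes in the deposited values. The median female minus male difference was -0.38, and 1060 of 1094 called genes were lower in females. Median centring moved that median to -0.05 and left 730 called genes, of which 307 were higher and 423 lower in females, and 145 genes were called in both with opposite directions. Quantile normalization gave 341 higher and 352 lower, median centring within each panel 291 and 336, and housekeeping centring 153 and 448. The genes with the smallest p, Prkcsh, Gnai2, Atcay, Cadm3 and Camk2b, were at -0.77, -0.56, -0.80, -0.72 and -0.70 as deposited and at -0.44, -0.23, -0.48, -0.39 and -0.38 after median centring, and at -0.29, -0.09, -0.33, -0.25 and -0.23 with median centring within each panel, still called. Females and males lay in separate blocks within every genotype, so sex and a separate run cannot be told apart.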

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

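Median centring within each panel, the filter at a mean of 20 counts, and the tests of the all-gene median, of the dimmest genes, of the balance of cell types and of the homeostatic score were chosen only after the data or the result had been seen.

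The first pattern is the breadth of the P522R difference, 828 of 1266 genes. Centring each panel of each mouse on its median gave 847 calls, 730 of them among the 828 in the same direction, which argues against a single scaling factor per mouse, and 745 calls stood among genes with a mean of 20 or more counts, which argues against a raised floor as the whole account. For the lymphocyte genes a raised floor may suffice, since the 100 dimmest genes rose by 0.77 at the median, near the 0.89 of that list. Genes of neurons, astrocytes and oligodendrocytes were compared with microglial genes over list members with a mean log2 value of 6 or more. They were called 1.61 times as often as microglial genes in P522R mice (69 of 91 against 25 of 53, Fisher's exact test, two-sided, p = 0.000966, over genes that are not independent), whereas in M28L mice the ratio was 0.35. In the same order of gene sets, the median absolute log2 fold changes were 0.25 and 0.19 in P522R mice and 0.09 and 0.22 in M28L mice. The share called also depends on how precisely genes are measured, and the sets were not matched for that. A separate run or normalization of the P522R mice would go with that balance of calls. It stays open beside an effect of the variant, which no comparison here separates from it.

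The second pattern is the lower disease-associated microglia score in M28L mice. The score fell by more than the homeostatic score, by a further -0.34 log2 (permutation within sex, p = 1e-05, the smallest 100000 resamples can give), which argues against fewer microglia of every kind as the whole account. The median of all genes differed by 0.0006, against scaling, and the M28L mice with index 1 to 3 and with index 7 to 9 stood at -0.41 and -0.47, against a single set of mice. A lower plaque-associated state of microglia in M28L mice is a hypothesis that stays open, with plaque load not analysed here and the order of collection not given.

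The third pattern is the higher immediate early genes in M28L mice. All 12 M28L mice lay above the 5xFAD mean of their sex, against a few mice carrying the list, and the sets with index 1 to 3 and 7 to 9 stood at 0.42 and 0.34. Handling before collection might raise these genes too, was not given in the labels and was not tested; an effect of the variant itself also stays open as a hypothesis. In P522R mice 9 of 12 lay above 0, with a mean score of 0.39 ± 0.35 (SD, n = 12) against 0.38 ± 0.16 (SD, n = 12) in M28L mice. Of the 9 members 6 rose and 0 fell in P522R mice, and camera did not call the list (adjusted p = 0.455). Of all 1266 genes 513 rose and 315 fell in P522R mice, and no value here separates that variant from its block. Higher scores were thus seen in most P522R mice too, but a response common to both variants is not shown. Both variants were set against the same 12 5xFAD mice.

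Random splits of the same mice, within sex or, for the sex comparison, within genotype, gave the share of 100 splits with a count as large, the real split included. For M28L against 5xFAD 1 split did, the real count being 130 and the highest other 0, so a chance split is unlikely. A share of 1 in 100 is the smallest that this test can give. The P522R and sex counts may still hold a difference between blocks of mice. A chance split is likewise unlikely for P522R against 5xFAD (1 split, 828 against a highest other of 529), P522R against M28L (1 split, 856 against 313) and females against males (1 split, 1094 against 317). It is also unlikely for M28L in males (1 split, 26 against 1), P522R in females (1 split, 762 against 539) and P522R in males (1 split, 640 against 412). Chance is not excluded for M28L in females (8 splits, 49 against a highest other of 188, several times the real count, which points to structure among these females). M28L_5xFAD_F replicate 20, looked up after the values were seen, stood at 11.28 on the second principal component against 1.55 to 6.08 in the other M28L females, and without it 43 genes changed in females; whether it makes that split was not tested. The splits decide nothing for the P522R interaction with sex (5 splits, 264 against 629), as a split that exchanges genotypes in a single sex carries the P522R main difference into the interaction. For the lists called in M28L mice 11 splits gave as many (5 against a highest other of 8), so chance is not excluded there either. Where the real count is 0 all 100 splits give as many by construction, so the splits say nothing about chance for the M28L interaction (highest other 2) or for the lists in P522R mice against 5xFAD and against M28L (highest other 8 in each).

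The P522R effect differed between females and males for 264 genes by the interaction test, which cannot be told apart from a difference between the blocks of mice. The female minus male differences were 0.87 for Rnf10, 0.60 for Ptpn11, 0.73 for Atcay, 0.69 for Tln2 and 0.62 for Camk2b. Of 120 tests for a mouse far from the rest of its group, each of a list score or of the median of all genes in a group of 6 mice, 4 found one, where chance gives about 6. M28L_5xFAD_F replicate 12 stood apart in the disease-associated microglia score, at -0.68 against -0.45 to -0.33 in the others, a gap of 0.66 of the range, and in the lipid handling score, at -0.38 against -0.03 to 0.14, a gap of 0.67. P522R_5xFAD_M replicate 27 stood at -0.25 in the oligodendrocyte and myelin score against -0.06 to -0.01, a gap of 0.79. P522R_5xFAD_F replicate 106 stood at 0.06 in the neuron and synapse score against 0.13 to 0.18, a gap of 0.63.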

How the results depend on the processing

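Median centring within each panel, the filter at a mean of 20 counts, housekeeping centring of the sex, interaction and within-sex comparisons, and list tests without the third genotype were chosen after seeing the data. Each count of genes or lists not given here stayed within 1.5 times its value, over up to 15 alternatives. For M28L against 5xFAD, 130 genes became 306 with housekeeping centring, 30 without a sex term and 77 with the M28L mice of index 1 to 3. The first rests on Gusb and Tbp alone, of which Gusb itself fell by 0.47 in M28L mice, and moved the all-gene median to 0.17; the second puts the difference between the sexes into the spread, and the third has fewer mice. Housekeeping centring ended the call of Gria3, at 0.00 (adjusted p = 0.985). Females against males, 1094 genes, became 693 with quantile normalization, 627 with median centring within each panel and 601 with housekeeping centring, which also gave 270 for M28L in females, 419 for P522R in males and 56 for the P522R interaction. The 5 lists called in M28L mice became 0 with an estimated correlation. Lists called in P522R mice against 5xFAD went from 0 to 1 with quantile normalization, 2 with housekeeping centring and 8 with fry, and against M28L from 0 to 2, 3 and 12; the cause was not tested. The correlation of fold changes, 0.25, became 0.15 with quantile normalization, 0.05 with the filter at a mean log2 of 5, 0.10 with the filter at 20 counts and 0.18 with split controls, so low genes carry much of it.

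Leaving out each mouse in turn gave 100 to 157 genes for M28L, 788 to 851 for P522R, 834 to 884 for P522R against M28L, 1083 to 1117 for sex, 0 to 0 and 211 to 302 for the M28L and P522R interactions, 29 to 68 and 15 to 32 for M28L in females and males, 700 to 788 and 566 to 673 for P522R in females and males, 5 to 6 lists for M28L, 0 to 0 lists for both P522R comparisons, and a correlation of 0.19 to 0.31, lowest without M28L_5xFAD_F replicate 14-F1 and highest without M28L_5xFAD_F replicate 20. The 5 lists called in M28L mice were called in all 36 of these fits, and the neuron and synapse list in 8. For named genes, 2896 of 3061 values under the alternatives kept direction and call, 136 lost the call, 13 gained it, 14 changed sign without a call and 2 lost both the call and the sign. Of the lost calls, 32 came without a sex term and 22 each with housekeeping centring and with the M28L mice of index 7 to 9. The index numbers did not pair mice: deviations of 22 pairs with a shared index and sex had a median correlation of -0.06, and 2 were over 0.1. With the index as a replicate block 97, 765 and 755 genes were called for M28L, P522R and P522R against M28L. No 5xFAD mouse had an index of 7 to 9, so M28L mice of those indices had no 5xFAD mouse in their block. The M28L contrast in that fit thus rested largely on the M28L mice of index 1 to 3, and calls can be lost through fewer mice. P522R_5xFAD_F replicate 8, which has no index, was left out of it. With that block adjusted p in M28L mice was 0.16 for Trem2, 0.0986 for Tyrobp, 0.0563 for Gfap, 0.125 for Serpina3n, 0.0751 for Cx3cr1, 0.223 for Tmem119, 0.095 for Slc2a1, 0.119 for Csf3r, 0.181 for Pla2g4d and 0.154 for Tnfrsf10b, and 0.145 for Trem2 in P522R mice, none of them called. Genes under about 20 counts sit near the floor, and their fold changes are limited by it.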

Other observations

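The tight junction gene Cldn5 of brain endothelium fell by 0.55 ± 0.09 (SE) in M28L mice and by 0.48 ± 0.09 (SE) in P522R mice, with adjusted p = 4.03e-05 and 1.31e-05 in limma, lower in 12 and 11 of 12 mice. The glucose transporter gene Slc2a1 rose by 0.40 and the endothelial gene Nostrin by 0.50 in M28L mice, where of 12 measured endothelial and mural genes 2 rose and 1 fell (2 and 2 adjusted over the list alone). In P522R mice 4 rose and 2 fell (4 and 1 adjusted over the list alone), with the pericyte receptor gene Pdgfrb at 0.49. Camera did not call the list in M28L or P522R mice (adjusted p = 0.97 and 1, and adjusted p = 1 and 1 with an estimated correlation). In M28L mice the calls of Slc2a1 and Nostrin ended without a sex term (adjusted p = 0.535 and 0.313), and with index 1 to 3 for Slc2a1 (0.0646) and 7 to 9 for Nostrin (0.236); a pseudocount of 20 took Nostrin to 0.32, still called.

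In M28L mice the lipase gene Lpl fell 1.49-fold (adjusted p = 6.36e-06 with limma, lower in 12 of 12 mice) as the called member of 7 lipid handling genes (1 adjusted over the list alone), while Lrp1 stood at -0.06. Of 12 measured members of the TREM2 to PLCG2 signalling list 3 fell (4 adjusted over the list alone), namely Trem2, Tyrobp and the cytokine receptor gene Csf3r. The median of the list was -0.03 against a mean of -0.15. The myeloid transcription factor gene Spi1 fell by 0.33, and of 15 amyloid and AD genes 3 fell (adjusted over the list alone, 3 fell and 1 rose). Of 20 oligodendrocyte and myelin genes 1 fell, Plxnb3 at -0.29 (1 adjusted over the list alone). The call of Plxnb3 ended with quantile normalization and with median centring within each panel (at -0.23 in each, adjusted p = 0.0751 and 0.0846), without a sex term (adjusted p = 0.433), with index 1 to 3 or 7 to 9 (0.0527 and 0.22) and on leaving out some single mice. Of 19 inflammatory genes Tlr2 fell by 0.53 and Nfkbia rose by 0.47 (1 and 1 adjusted over the list alone), and of 5 peripheral myeloid genes Csf3r fell (1 and 1 adjusted over the list alone). Centring on housekeeping genes ended the calls of Spi1, Plxnb3 and Csf3r, at -0.16, -0.12 and -0.26 (adjusted p = 0.138, 0.344 and 0.0911). That of Csf3r also ended without a sex term (adjusted p = 0.118), with index 7 to 9 (0.281) and on leaving out some single mice.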
